A study of Mus musculus with 2 samples.

How the data were processed

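Total RNA sequencing of hippocampus from aged female mice of the B6CASTF1/J strain, the first-generation hybrid of C57BL/6J and CAST/EiJ, was analysed from deposited tables. The animals were 18 to 20 months old and each library was made from 300 ng of RNA, per the labels. Ribosomal RNA was reduced and ERCC spike-in RNAs, synthetic transcripts of known sequence, were added, per the labels. The labels give 1 group of 2 libraries, numbered as biological replicates 1 and 2. Each has its own biosample label and both carry the same donor label, so whether the tissue came from separate animals cannot be read from the labels. No contrast between groups exists, so no p-value was computed, and differences between the 2 libraries describe those libraries.

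The deposited gene table holds an expected count per gene, which is an estimated number of reads that need not be whole, together with a posterior mean count. The same table gives the authors' TPM, an abundance corrected for effective length that sums to 1000000 over a library, and FPKM, reads scaled by effective length and library size. Deposited transcript tables of the same layout give the expected count, TPM, FPKM and the percent of each gene's abundance taken by each transcript. A second deposited transcript table gives an estimated count and TPM made from the reads without a separate alignment. Per the file headers, the column names are those written by RSEM for the former and by kallisto for the latter, and the layouts are named so here. The build was mm10 and the annotation GENCODE M21, per the deposited notes that accompany the tables. The aligner, the program versions and the strand setting are not given in the sources used here. Reads of overlapping and antisense genes, such as Xist and Tsix, may therefore have been shared. The GENCODE M21 annotation supplied symbols, biotypes and 1-based coordinates, and all 55536 gene rows matched it. Of these genes, 86 had no transcript in the kallisto-layout tables.

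Expected counts were rounded to whole numbers. Gene-assigned counts were 35358140 in replicate 1 and 36307291 in replicate 2. ERCC rows, 1 phiX row and 26248 numbered rows without a gene name were kept out of library sizes, and the numbered rows held 2.78 counts in replicate 1 and 6.00 in replicate 2. Libraries were scaled with TMM factors after filterByExpr in edgeR 4.0.16 under R 4.3.3. The common dispersion was estimated with an intercept-only design, and its square root is the biological coefficient of variation. Log2 ratios are replicate 2 minus replicate 1 with a prior count of 2. Folds of single genes used scaled counts without a prior, with exact 95% binomial intervals conditional on the sum of both counts. A gene at 0 in 1 library was given a bound from a floor of 3 counts in that library. Shares of counts in 1 library have exact Clopper-Pearson 95% intervals. Reads carried no molecular identifiers in these tables, so intervals and floors cover counting error only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

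A gene counted as detected at a TPM of at least 1 in both libraries. A gene was called apart when its scaled counts differed over 2-fold and its mean count was at least 50. For each of 35 gene lists the median TPM per library was computed. The median log2 ratio was taken over members with a mean count of at least 10 and placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its percentile was under 2.5 or over 97.5, and at least 4 members were needed. Rmrp has 2 identifiers in the annotation and both were used. The leading isoform of 12 genes was the transcript with the largest mean share of the gene's TPM.

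The lists, thresholds and most alternatives were fixed before the data were examined. So was the rule for named genes. It covers the 20 protein-coding nuclear genes and 10 genes of other biotypes with the highest mean TPM, and the 12 isoform genes. From each list it takes up to 4 members of highest mean TPM, the lowest member and any member called apart. It adds the 10 largest ratios in each direction, Xist with the Y-linked genes, and the spike-ins as a class. Genes outside the rule are marked in the text, and some genes within it are not reported here. Alternatives were DESeq2 1.42.0 size factors, library totals, ERCC totals, other count and TPM minimums, pseudocounts and prior counts, means in place of medians, TPM, FPKM or posterior mean counts, the kallisto-layout tables, and each library alone. Restrictions to genes called in both layouts, to named genes and to protein-coding genes were chosen after seeing the data.

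The procedure was tested on simulated data for the 2 libraries, with 55536 genes drawn at their real means and a coefficient of variation of 0.1. Of 200 genes changed 4-fold, 97.0% passed the 2-fold rule in the right direction, as did 4 unchanged genes among 14302 with a mean count of at least 50. The coefficient of variation was estimated at 0.1002. A planted list of 12 genes raised 1.5-fold came out at percentile 100, and 5 of 100 random lists fell outside the percentiles. Simulated genes varied independently, so this does not cover lists whose members vary together.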

Results

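The data comprise total RNA profiles of hippocampus from aged female B6CASTF1/J mice, in 2 libraries of 1 group. The labels describe the tissue and no treatment, so the values show which transcripts the tissue held and how closely 2 libraries of it matched. Gene-assigned expected counts summed to 35358140 in replicate 1 and 36307291 in replicate 2. ERCC spike-ins took 0.493% of all counts in replicate 1 (exact 95% interval 0.491 to 0.495) and 0.489% in replicate 2 (0.487 to 0.492). Values below are the mean ± SD of both libraries (n = 2) unless a library is named.

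Nuclear protein-coding RNA was led by genes of iron storage, translation, the cytoskeleton and synaptic signalling. In the RSEM-layout TPM, Fth1, the ferritin heavy chain, stood highest at 1390 ± 73.6 TPM (SD, n = 2), followed by the elongation factor gene Eef1a1 at 1307 ± 16.1 TPM. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, reached 1305 ± 38.8 TPM, which differed from Eef1a1 by less than the spread between libraries. The order depended on the quantification, and in the kallisto layout Gapdh stood at 3276 and 3301 TPM, above Fth1 at 2617 and 2458 TPM. Actb was at 1238 ± 57.0 TPM and Apoe, the main lipid carrier of the brain, at 1073 ± 60.5 TPM. The calmodulin genes Calm2 and Calm3 were at 858 ± 35.1 and 845 ± 22.3 TPM, closer to each other than their spread. Hpca, which encodes the calcium sensor hippocalcin, was at 872 ± 85.1 TPM and the synaptic vesicle fusion gene Snap25 at 901 ± 8.67 TPM. Atp1b1, a sodium pump subunit gene, was at 766 ± 21.9 TPM. Snurf, at 893 ± 31.4 TPM, was listed at 0 in the kallisto-layout tables in both libraries.

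Structural RNAs lay far above these genes. The signal recognition particle RNA genes Rn7s1 and Rn7s2 held identical values of 154382 ± 8450 TPM, and their reads cannot be divided between the copies. Rn7sk, a regulator of transcription elongation, was at 56730 ± 374 TPM, and the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were at 45764 ± 2079 and 34433 ± 1895 TPM. Gm26917 stood at 12439 ± 439 TPM. The pseudogenes Gm28661, Gm10925 and Gm28437 reached 7392 ± 116, 6236 ± 183 and 4602 ± 437 TPM. They are annotated side by side on chromosome 1 and may share reads with near copies. Those copies were not identified, so these values may hold reads of other genes. Rn7s1, Rn7s2, Rn7sk and Rpph1 together held at most a few counts each in the kallisto-layout tables, so their level depended on the quantification.

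Protein-coding genes took 80.5 ± 0.212% of gene-assigned counts. The 13 mitochondrially encoded ones among them took 1.96 ± 0.0774% of all gene-assigned counts. Mitochondrial rRNA took 7.16 ± 0.143%, misc_RNA, the class of Rn7s1, Rn7s2 and Rn7sk, 5.54 ± 0.401%, and lincRNA 4.45 ± 0.118%. Within the lincRNA class, Gm26917 alone held 870985 of 1603512 counts in replicate 1 and 881693 of 1586145 in replicate 2. The share of the class therefore rests largely on this gene, and the origin of its reads was not tested. The protein-coding share was 44.1% when computed from TPM, which weights short RNAs more heavily. Of TPM, protein-coding genes took 45.0% in replicate 1 and 43.3% in replicate 2, and misc_RNA 35.7% and 38.1%. The TPM of a gene can therefore be lower in replicate 2 where its scaled counts are not. Camk2a, for example, was at 1333 and 1278 TPM but 1.01-fold higher in replicate 2 by scaled counts. In all, 14369 genes had a TPM of at least 1 in both libraries, among them 12733 protein-coding genes and 262 lincRNA genes. The count was 14881 in replicate 1 and 14757 in replicate 2.

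Markers of neurons and glia were detected in both libraries. List levels are those of the RSEM layout, and in the kallisto layout the 21 marker lists were a median of 1.69-fold higher. TPM sums to a fixed total, of which misc_RNA took 35.7% and 38.1% in the RSEM layout. In kallisto-layout counts this class took 0.000198% and 0.000290%. Its near absence there alone raises the TPM of other genes, so the 1.69-fold shift is no measure of marker expression. The excitatory neuron list had a median of 335 TPM in replicate 1 and 297 TPM in replicate 2, and all 7 members exceeded 1 TPM. Its members Nrgn and Slc17a7, the latter encoding a vesicular glutamate transporter, were at 587 ± 45.9 and 525 ± 22.6 TPM. GABAergic interneuron markers had medians of 25.3 and 24.4 TPM, and the ratio of the 2 lists was 12.7 ± 0.771. Sst and Gad1 led the interneuron list at 182 ± 11.3 and 150 ± 3.96 TPM. Astrocyte medians were 85.3 and 83.3 TPM, with the glutamate transporter gene Slc1a2 at 689 ± 20.6 TPM and Gfap at 188 ± 9.28 TPM. Microglial medians were 19.2 and 19.4 TPM, with Csf1r at 31.9 ± 0.0778 TPM. Oligodendrocyte medians were 51.1 and 36.5 TPM, and precursor medians 7.56 and 6.67 TPM, led by Pdgfra at 14.4 ± 1.22 TPM. Endothelial medians were 7.61 and 8.41 TPM, led by Ly6c1 at 24.9 ± 0.891 TPM.

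Of the hippocampal fields, CA1 pyramidal cell markers had the highest list medians at 48.8 and 40.1 TPM. CA3 markers were at 17.9 and 18.6 TPM, dentate granule cell markers at 12.4 and 11.3 TPM and CA2 markers at 9.22 and 7.91 TPM. The ratio of CA1 to CA2 was 5.18 ± 0.153 and that of CA1 to CA3 2.44 ± 0.401. These lists hold different genes, so their ratios do not measure cell numbers. Mpped1 and Wfs1 led CA1 at 79.4 ± 0.665 and 56.5 ± 2.79 TPM, Pcp4 led CA2 at 101 ± 7.95 TPM, and C1ql2 and Prox1 led the dentate list at 41.6 ± 2.58 and 33.7 ± 0.0707 TPM. Bok and Grik4 led CA3 at 21.4 ± 2.10 and 21.2 ± 1.37 TPM, closer to each other than their spread. Markers of immature neurons and dividing cells lay at medians of 0.39 and 0.175 TPM. Within that list Neurod1 was at 11.7 ± 0.233 TPM and Dcx, a gene of migrating young neurons, at 3.38 ± 0.304 TPM, and Eomes held 9 counts in replicate 1 and 1 in replicate 2.

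Markers of adjoining regions and other cells were also measured. Neocortical markers had medians of 7.78 and 8.81 TPM, thalamic markers 3.12 and 3.75 TPM and striatal markers 1.60 and 1.99 TPM. Mural cell medians were 2.10 and 3.82 TPM, ependymal medians 2.02 and 1.49 TPM, and lymphocyte medians 0.03 and 0.09 TPM. Erythroid medians were 102 and 144 TPM, with the globin gene Hba-a1 at 155 ± 49.3 TPM. Of 21 marker lists, 18 had a median of at least 1 TPM in both libraries. The exceptions were lymphocytes, immature neurons and dividing cells, and choroid plexus epithelium, which lay at 1.44 TPM in replicate 1 and 0.985 TPM in replicate 2.

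**Figure D1:**
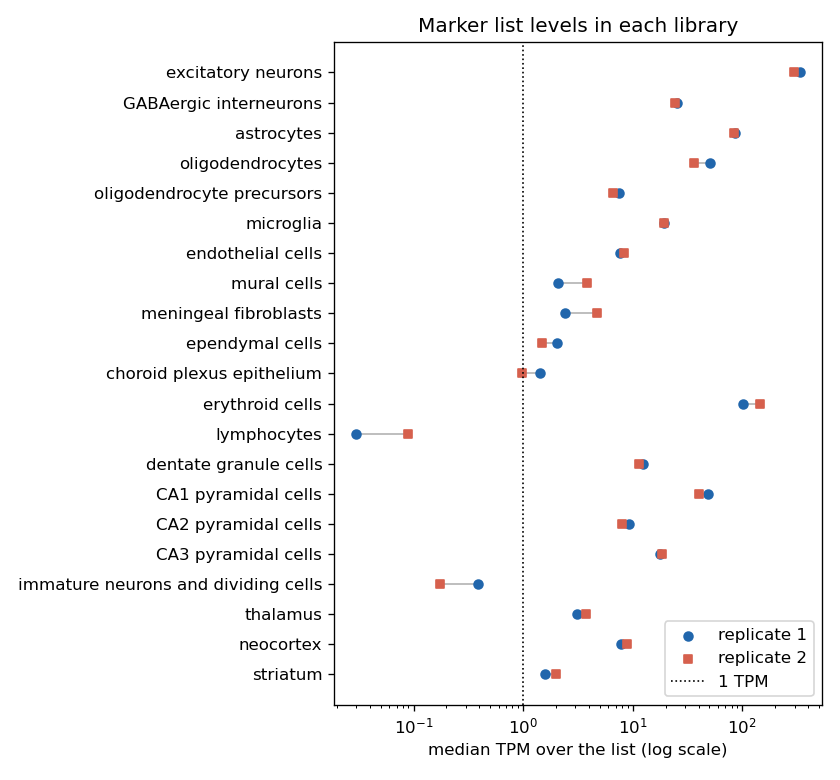
Median TPM over the members of each of 21 marker lists, on a log axis, in replicate 1 (circles) and replicate 2 (squares), with a dotted line at 1 TPM. Excitatory neuron markers sit highest, at 335 and 297 TPM, and lymphocyte markers lowest, at 0.03 and 0.09 TPM.

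The 2 libraries were close across genes. Pearson's r of log2(TPM + 1) over 55536 genes was 0.996 and Spearman's rho 0.941, and genes are not independent replicates. The biological coefficient of variation was 4.66% over 17697 genes. Of 14307 genes with a mean count of at least 50, 89.6% lay within 1.2-fold. The chi-square per degree of freedom, which is near 1 for counting noise alone, was 6.22 over genes and 1.93 over ERCC spike-ins. Spike-ins entered at a lower minimum count than genes, and counts were not matched between the 2 sets, so these values are not directly comparable. Rows of high count weigh heavily, such as Rn7s1 and Rn7s2 with 761057 and 878983 counts each, so 6.22 is not typical of a gene.

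Xist, the noncoding RNA that coats the inactive X chromosome, differed between the libraries. Xist (ENSMUSG00000086503.4, mm10 chromosome X, 103460366 to 103483254, minus strand) held 57455 counts in replicate 1 and 27714 in replicate 2. It was 2.12-fold higher in replicate 1 (exact 95% counting interval 2.09 to 2.15), and its log2 ratio of -1.09 compares with a median absolute log2 ratio of 0.07 over genes. Its antisense partner Tsix held 51 and 49 counts. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together held 2 counts in replicate 1 and 4 in replicate 2, at or near the floor of 3 counts.

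Markers of meningeal fibroblasts, the cells of the brain's covering, were higher in replicate 2, with a median log2 ratio of 1.05 at percentile 100. All 8 members were higher there, and 6 of them over 2-fold. Igf2 (chromosome 7, 142650766 to 142666816) held 925 and 2100 counts, 2.22-fold higher in replicate 2 (2.05 to 2.40). Col3a1, a fibrillar collagen gene, was 2.52-fold higher (1.91 to 3.38) and Aldh1a2, which encodes a retinoic acid synthesis enzyme, 2.40-fold higher (1.93 to 2.99). Col1a1 and Slc6a13, at 2.04 and 2.03-fold, fell below the 2-fold rule in the kallisto-layout counts and in the TPM as deposited, as did Col1a2 in the latter. Erythroid markers were also higher in replicate 2, with a median log2 ratio of 0.66 and all 5 members higher, as were mural cell markers at 0.47. Endothelial markers stood at 0.19, neocortical markers at 0.25 and MHC class I genes at 0.55, with H2-K1 1.52-fold higher (1.30 to 1.77). Mitochondrially encoded proteins stood at 0.12 and microglial markers at 0.08, and the microglial list no longer stood apart with means of members or kallisto-layout counts.

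Choroid plexus markers were lower in replicate 2, with a median log2 ratio of -0.91 at percentile 0, or -0.60 over members with a mean count of at least 50. Of 10 members 9 were lower and 1 higher, and 2 were called over 2-fold apart. Ttr, the transthyretin gene (chromosome 18, 20665280 to 20674321), held 4171 counts in replicate 1 and 1456 in replicate 2, 2.93-fold higher in replicate 1 (2.76 to 3.12). Clic6 was 2.25-fold higher there (1.69 to 3.02). Oligodendrocyte markers were lower in replicate 2 as well, at a median of -0.35 with all 10 members lower, among them the myelin gene Mbp at 1.32-fold higher in replicate 1. Glucocorticoid-responsive genes stood at -0.30, with Plin4 2.54-fold higher in replicate 1 (2.26 to 2.87) while Sgk1 was 1.44-fold higher in replicate 2. Immature neuron and dividing cell markers stood at -0.28, with 3 of 6 counted members lower and 3 higher in replicate 2, CA1 markers at -0.13 and excitatory neuron markers at -0.10. The 3 lower members of the immature list held at most 20 counts in either library. With a mean count minimum of 50, too few members remained to place that list. The CA1 list no longer stood apart with means of members, and the immature list no longer with kallisto-layout counts. In all, 14 of 33 testable lists stood apart, 8 higher in replicate 2 and 6 higher in replicate 1. If members varied independently, 1.65 would be expected outside the percentiles. Markers of a cell type can vary together, so 1.65 is no measure of chance for these lists.

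**Figure D2:**
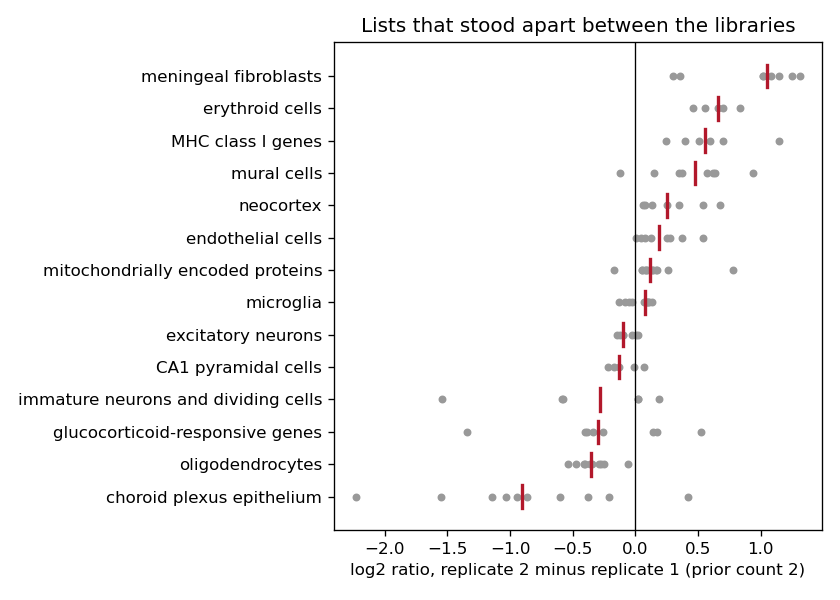
Log2 ratio of replicate 2 to replicate 1 for the members (grey points) and the median (red bars) of the 14 lists that stood apart. Meningeal fibroblast markers lie highest, with a median of 1.05, and choroid plexus markers lowest, with a median of -0.91.

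Of the 14307 genes tested, 55 were over 2-fold apart, 33 higher in replicate 2 and 22 higher in replicate 1. Many were pseudogenes or numbered models, which made up 26 of the 55, and 8 had 0 counts in 1 library. Gm6565, a processed pseudogene, held 343 counts in replicate 1 and 0 in replicate 2, at least 117-fold higher in replicate 1, and Rpl15-ps3 was at least 85.0-fold higher there. Gm6361 held 0 and 373 counts. All 3 of these pseudogenes were listed at 0 in both kallisto-layout libraries, and a processed pseudogene can share reads with the gene it copies. Of the 55 genes, 24 were also over 2-fold apart in the same direction in the kallisto-layout counts with a mean count of at least 50 there. Among these, Fmod was 3.43-fold higher in replicate 2 (2.80 to 4.23) and Dsc3 3.01-fold (2.24 to 4.10). Ptgds, a prostaglandin D2 synthase gene named after its values were seen, held 4314 and 10265 counts, 2.32-fold higher in replicate 2 (2.24 to 2.41).

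**Figure D3:**
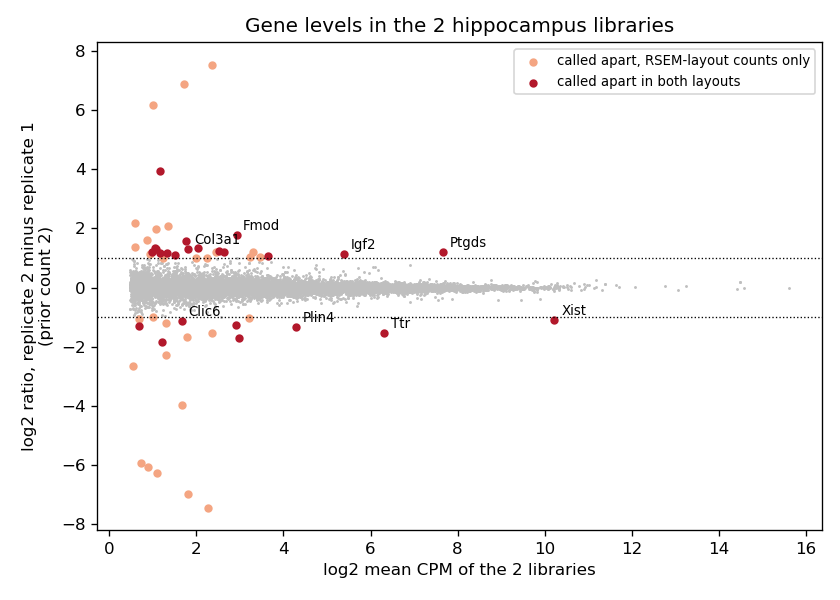
Log2 ratio of replicate 2 to replicate 1 against log2 mean CPM for genes with a mean count of at least 50, with dotted lines at 2-fold. Dark points are the 24 genes over 2-fold apart in the same direction with a mean count of at least 50 in both count layouts, among them Xist at -1.09 and Igf2 at 1.15.

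Isoform use was close between the libraries for 12 neuronal and glial genes. The leading isoform was the same in both libraries for all 12 genes, and the same in both libraries and both layouts for 10. App-201 took 90.8 ± 0.340% of App and Snap25-201 took 85.7 ± 0.299% of Snap25. Mapt-204 took 69.0 ± 2.07% of the tau gene Mapt, and Camk2a-203 63.1 ± 0.586% of Camk2a. Gria1-201 and Gria2-202 took 52.3 ± 3.14% and 55.7 ± 1.10% of these AMPA receptor genes. Ntrk2-202, Map2-204 and Homer1-207 led their genes with 32.7 ± 0.0930%, 42.2 ± 0.222% and 31.2 ± 0.0130%. Mbp-211 took 68.4 ± 1.97% of Mbp, against 37.5% in the kallisto layout. Grin1-201 led Grin1 with 38.0 ± 0.996%, while Grin1-205 led in the kallisto layout with 32.0%. Bdnf-205 took 40.1 ± 2.72% of Bdnf, and in the kallisto layout the leading isoform of Bdnf differed between the libraries.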

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

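The gene table holds 26248 numbered rows that name no gene and entered no comparison, of which 26185 have an effective length of 0. These rows held 6.00 counts in replicate 2, above the 3 counts that a count of 0 allows, and 2.78 counts in replicate 1, below it. They carried counts in 3 rows in replicate 2 and in 2 rows in replicate 1. No explanation was tested.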

How the results depend on the processing

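Restrictions to genes called in both layouts, to named genes and to protein-coding genes were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because the samples form 1 group, and leaving out a library ends any comparison between libraries. The number of genes over 2-fold apart, 55, was 55 to 56 under the other scalings, 69 with the TPM as deposited and 46 with the kallisto-layout counts. It was 437 with a mean count minimum of 10 and 15 with a minimum of 200, where more and fewer genes were tested. It was 24 when both layouts had to pass and 28 for named protein-coding and lincRNA genes, since these rules only remove genes. The correlation moved from 0.9959 to 0.9892 with a pseudocount of 0.1, to 0.9889 over genes with a mean TPM of at least 1 and to 0.9963 with FPKM; the cause was not tested. The protein-coding share was 44.1% by TPM, 85.7% in the kallisto layout and 86.4% without mitochondrial genes, which leave the denominator. In the kallisto layout misc_RNA fell from 5.26% to 0.000198% of counts in replicate 1 and from 5.83% to 0.000290% in replicate 2. A smaller class raises the shares of the others, but whether this accounts for the whole rise was not tested. With 1 library left out, the protein-coding share ranged from 80.3% to 80.6%, detected genes from 14757 to 14881, marker lists detected from 18 to 19 and matching leading isoforms from 10 to 11. A median TPM of at least 5 left 13 marker lists, and shares of expected counts left 9 matching isoforms, without Mbp. Detected genes ranged from 12733 to 20690 over all alternatives, lists apart from 13 to 16, and the coefficient of variation from 4.66% to 4.89%. Among single genes apart, the last 3 below named after their values were seen, Gm4070 turned to a log2 ratio of -0.30 by TPM. In kallisto-layout counts Gm14308 turned to 0.80, Gm49378 to 0.021 and Myl12b to -0.67, and the cause was not tested. Lists that stood apart still did in 93 recomputations and did not in 4, where the median or mean kept its sign. List levels in TPM moved beyond the spread of the libraries in the kallisto layout for 34 of 35 lists. Of the 35, 34 were higher there and 1 lower, the long noncoding and structured RNAs, at 21.8 against 1643 TPM. With misc_RNA nearly absent in that layout, the fixed TPM total raises the TPM of other genes, so these rises need not reflect the lists themselves. Depth limits genes near the floor of 3 counts, such as the Y-linked genes.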

Other observations

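The tests of male cells, of nuclear RNA yield, of a lower share of neurons, of RNA copies and of RNA classes were chosen only after related values were seen, and the other tests before, though the lower ERCC total in the kallisto layout was known when the spike-in test was set. The design names a single group, so no biological explanation that sets groups apart was tested. Standard errors of medians below are taken over the member genes within this pair of libraries. They do not measure spread between samples, and members of a list can vary together.

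Several gene groups lay within the percentiles that matched random lists span. Cytosolic ribosomal protein genes had a median log2 ratio of 0.01, with Rpl4 at 266 ± 7.21 TPM (SD, n = 2), nuclear oxidative phosphorylation genes 0.02, led by Atp5b at 726 ± 30.8 TPM, and glutamate and GABA receptor subunits 0.01, led by Gria1 at 277 ± 14.8 TPM. Circadian clock genes stood at -0.03, led by Tef at 117 ± 4.16 TPM. Immediate early genes stood at -0.07 and percentile 2.88 with 10 of 11 members lower in replicate 2, led by Arc at 65.9 ± 6.77 TPM. Imprinted genes stood at 0.03, led by Meg3 at 794 ± 46.1 TPM, and the long noncoding and structured RNAs at 0.01, with Malat1 at 3603 ± 192 TPM. Interferon-responsive genes stood at 0.04, activated glia genes at -0.05 with Spp1 2.20-fold higher in replicate 2 (1.62 to 3.01), and cyclin-dependent kinase inhibitors at -0.13, with Cdkn2a at 5 and 8 counts. Further list medians were 0.02 for GABAergic interneurons, 0.03 for astrocytes, -0.07 for oligodendrocyte precursors, -0.22 for ependymal cells, 0.01 for dentate granule cells, -0.10 for CA2, -0.02 for CA3, 0.12 for thalamus and 0.13 for striatum. The lymphocyte list and the female and male marker list had too few counted members.

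Xist was 2.12-fold higher in replicate 1. Male cells in replicate 2 were argued against, since 4 Y-linked genes held 4 counts there (exact upper limit 10.2), where over 500 were needed. A lower yield of long nuclear noncoding RNA as large as the fall of Xist was argued against as well. Such RNAs, 8 in all, had a median log2 ratio of -0.049 (standard error 0.07), and the lowest, Neat1, was at -0.19 against -1.09 for Xist. Of the 8, 3 were higher in replicate 2, but these lie close together on chromosome 12 and are not independent, and the other 5 were lower. The percentile of the 8 among matched random lists was 1.8, outside the range used here, so a small fall of this set is not excluded. A candidate explanation that stays open is loss of the inactive X in part of the cells: 8 genes known to escape X inactivation were all lower in replicate 2, with a median of -0.35 at percentile 0, while 485 X-linked genes had a median of 0.02. Without Jpx and Ftx, neighbours of Xist that the rule for named genes does not cover, the median was -0.30, but a lower Xist level per cell or unequal choice of the CAST and B6 X chromosomes was not tested and stays open too.

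Meningeal, choroid plexus and oligodendrocyte markers moved apart between the libraries. A lower share of neurons in replicate 2 would raise all other types alike, and the meningeal and oligodendrocyte medians differed by 1.40 (standard error 0.18). Gene length was argued against, since medians of 20 length bins spanned only -0.01 to 0.02. The meningeal median was 1.05 after their removal, but values this small could hardly have moved it. Unequal amounts of adjoining tissue in the 2 dissections may contribute but was not settled. The 7 further meningeal markers had a median of 0.44 (standard error 0.22), with 6 higher in replicate 2 and 1 lower. The 6 counted choroid plexus markers of 7 had -0.67 (standard error 0.33), all lower in replicate 2. Each median was within its standard error of the bounds of 0.5 and -0.5 set beforehand. The lower meningeal marker was Col6a1, the one with the most counts, 1.25-fold higher in replicate 1 (1.16 to 1.35). The choroid plexus marker Tmem72 was at -1.28 but at -0.12 in the kallisto layout. Col6a1 and Tmem72 were named after their values were seen.

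Short noncoding RNAs were counted in one layout and hardly in the other. Sharing of reads between copies within the classes misc_RNA, snRNA, snoRNA and ribozyme was argued against, since sharing keeps the sum of a class while these 4 classes kept 0.0045% of their counts in the kallisto layout. Sharing with copies of other classes or names was not examined and stays open: of 5 short RNAs without an annotated copy of the same name, which together kept 0.0116%, 4 kept at most 0.261% and Terc, of 423 bases and 43 counts, kept 58.1%, and the bound of under 20% was held first against their sum and against each RNA only after these values were seen. Loss of transcripts shorter than the assumed fragment may account for this, but its test was not decisive. The 4 ERCC spike-ins shorter than 334 bases kept 0% of 51 counts, while longer ones kept 75.0%, below the 80% set beforehand. That 75.0% pools spike-ins from 494 bases up, among which the shorter ones tended to keep less. Among genes, all 53 shorter than 200 bases kept under 10% of their counts. The median share kept was 0.0289% at 300 to 400 bases, 72.1% at 400 to 600, 94.4% at 600 to 1000 and 106% at 1000 to 3000. Terc, at 423 bases, lies in the range with a median of 72.1%, so its share does not tell sharing from length. These values were seen after the tests.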
